A study of Mus musculus with 19 samples.

How the data were processed

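Single-cell expression was read in 9 libraries of CD8 T cells sorted from digested A223 tumours and from spleens, and 8 receptor libraries accompany them in the labels. Exome DNA and RNA of A223 cells grown in culture were read in 1 library each. Replicate 1 of each tumour state was made with the 3′ kit and the other expression libraries with the 5′ kit. Per the labels, the authors processed the single-cell reads with Cell Ranger and the A223 reads with BWA and GATK, whose versions are not given. The genome build is not given in the sources used here, and positions are printed as deposited. Of 19151 coding exome calls in genes matched by symbol to the RefSeq annotation of GRCm38.p6, 99.3% lay within the bounds of that gene.

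The deposited per-cell table holds the count of UMIs and the number of genes of each cell, summed by the authors over all genes without normalisation. The percent of UMIs from mitochondrial genes was deposited per cell by the authors. The S and G2M score of each cell are, per the file headers, those of cell-cycle scoring in Seurat, and the deposited phase call matched the rule of those scores in 100% of cells. Cluster names, clonotype labels and receptor similarity groups are the authors' own. No cell had 500 or fewer genes or 10% or more mitochondrial UMIs, so a filter at these values removed 0 cells. The authors' treatment of doublets is not given in the sources used here, and no doublets were called or removed. The deposited variant table holds, per the file headers, a called genotype in exome and RNA and the RNA coverage of each position as a read number without normalisation. The copies of this table given for the exome and the RNA sample were identical, and 1 was used. Exome depth, allele read numbers and gene expression per cell were not used here.

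The library was the replicate. Shares of cells per cluster and per phase, and medians of the per-cell measures, were computed in each library and averaged over libraries. Tumour states were compared with two-sided exact permutation tests, 3 libraries against 3 or, for receptor measures, 2 against 2. Tumours and spleens were paired by state and number and compared with two-sided exact sign-flip tests. Adjusted p-values are Benjamini-Hochberg values over the clusters, the measures, the clonotype comparisons or the lists. Shares of single libraries carry exact Clopper-Pearson 95% intervals, and a count of 0 is given with the limit that 3 counts would set. Both cover counting error only. Deviations of clusters from the state means correlated between tumour libraries of the same number at 0.907, 0.672 and 0.282, and between those of different number from -0.788 to 0.312. Numbers were therefore also used as a block, although 0.282 lies within that range and replicate 1 shares the 3′ kit.

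The clone measures were averaged over 1000 seeded draws of 1296 labelled cells, the size of the smallest library. Only named clonotypes have an identity in the labels, so entropy and the share of clones of 2 or more cells were not computed. Named clonotypes took the place of expanded clones. The groups dividing, exhausted and naive join clusters by the authors' names. These groups, the comparison of named with remaining cells, the comparisons within clonotypes and within receptor groups, the UMI strata, limma with a block, the 5 Mb windows and the tests on neighbouring genes and splice sites were chosen after the data were examined. Genotype calls of exome and RNA were compared in place of the allele fractions first planned. The remaining comparisons and tests were fixed before the data were examined, as were 14 gene lists.

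The variants were counted by class, base change, chromosome and 5 Mb window. Windows with 100 or more coding calls were called dense, and those with 20 or fewer sparse. Exome calls were compared with RNA calls at 20 or more RNA reads. Windows were also sorted by non-coding calls, with intervals from 2000 seeded draws of windows. The order of genes for the neighbour tests came from the same annotation, in which 3992 of 4304 symbols with a coding call were matched. Lists were tested with two-sided Fisher's exact tests on genes with a protein-changing exome call, among genes with any variant. They were antigen presentation, interferon pathway, DNA repair, squamous carcinoma, naive, effector, exhausted, cycling, interferon-stimulated, CD4 or regulatory, B cell, myeloid, NK and keratinocyte.

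All clusters were named. Clones were named if they were among the 3 largest of a library or had 5 or more cells in at least 2 tumour libraries. Genes with a protein-changing call in the lists for antigen presentation, interferon, DNA repair and squamous carcinoma were named. So were the 20 protein-changing calls with the most RNA reads that were called in both DNA and RNA. The minimums for exome depth and allele fraction that this rule also named could not be applied.

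Alternatives were limma on logit shares and log2 medians, the 5′ libraries alone, the replicate block, leaving out each library, pooled cells, no thinning, the beta chain alone, other RNA depths and another list background. Phase calls and scores could not be thinned to 1 depth. On simulated data with 200 features, limma called 100% of large shifts, 52.5% of small ones and 1.67% of unchanged features. The simulated features were independent and had 1 common spread. The 13 clusters share a total and differ in spread, so these rates do not carry over to them. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.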

Results

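The series asked how CD8 T cells differ between mice in which a transplanted squamous cell carcinoma regressed and mice in which it grew. The tumour was A223, a mouse carcinoma line that the labels call derived from C57BL/6, injected into C57BL/6J mice. CD8 T cells were sorted from tumours and spleens and read in 9 expression libraries. They came from 3 regressing tumours, 3 growing tumours, 2 spleens of mice with regressing tumours and 1 spleen of a mouse with a growing tumour. In all, 41099 cells carried a cluster name given by the authors, with 13 names. The tumour libraries held 1655, 7832 and 7276 cells in regressing replicates 1, 2 and 3, and 1790, 4262 and 1727 cells in growing replicates 1, 2 and 3. The spleen libraries held 6598 and 6020 cells in regressing replicates 2 and 3 and 3939 cells in growing replicate 3. Total UMIs ranged from 10611320 in regressing tumour replicate 1 to 58661165 in regressing tumour replicate 3. T cell receptor labels covered cells of 7 of these libraries, the 5′ ones. A223 cells grown in culture were read separately as exome DNA and as RNA, with 1 library of each.

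The largest difference in share between the tumour states lay in dividing CD8 T cells. The 3 clusters that the authors named Dividing together held 24.6% ± 3.41 of cells in growing tumours and 12.4% ± 1.69 in regressing tumours (SD, n = 3 each), a ratio of 1.98. Each of the 3 was higher in every growing library than in any regressing one. Dividing 1, of which 97.2% of cells were called in S phase, held 7.78% ± 0.908 of cells in growing tumours against 4.53% ± 1.44 in regressing ones. Dividing 2, a mixture of S and G2M calls, held 10.7% ± 1.47 against 4.70% ± 0.591. Dividing 3, of which 83.0% of cells were called in G2M, held 6.08% ± 1.05 against 3.17% ± 0.150. The interferon-stimulated cluster went the other way, with 3.28% ± 1.48 of cells in growing tumours and 6.10% ± 0.463 in regressing tumours. These were the 4 clusters of 13 whose library shares did not overlap between the states, where chance gives 10% of clusters for 3 libraries against 3. The 13 clusters share a total, so they are not 13 separate tests. Without growing replicate 1 there were 9, but fewer libraries make separation by chance more frequent.

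**Figure D1:**
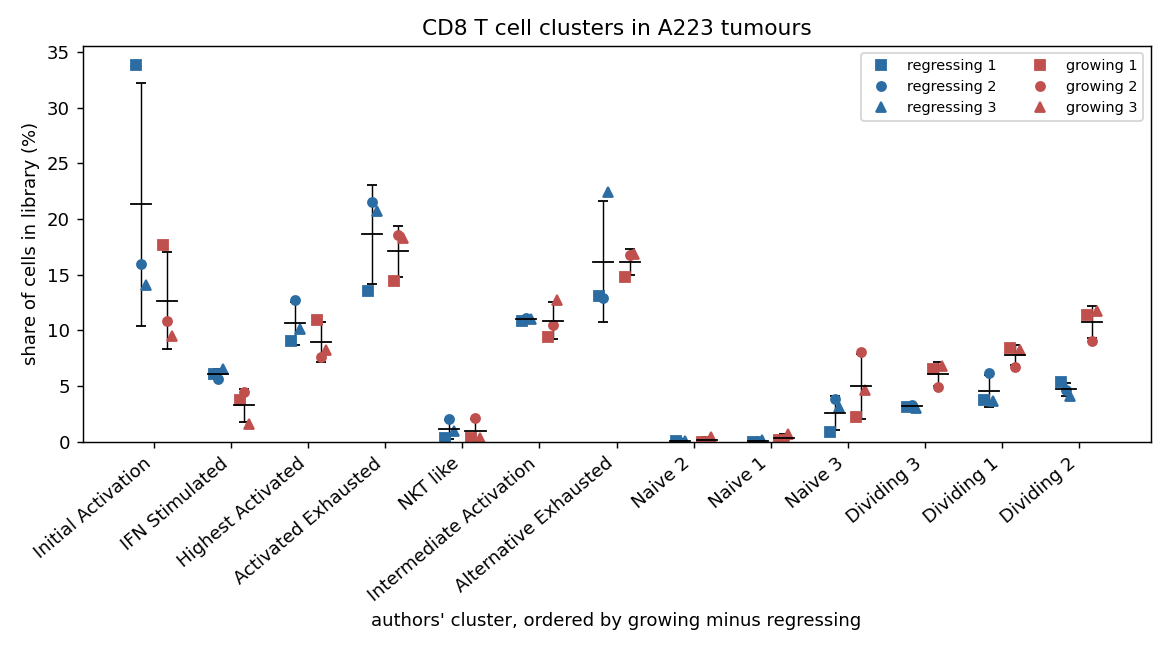
Share of each tumour library's cells (%, vertical axis) in the 13 clusters named by the authors (horizontal axis), with 1 point per library, blue for regressing and red for growing tumours, and black bars for the mean ± SD of 3 libraries. The 3 Dividing clusters lie higher in all growing libraries, at a mean of 10.7% against 4.70% for Dividing 2, and the interferon-stimulated cluster lies lower.

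Exhausted cells, the Activated Exhausted and Alternative Exhausted clusters together, differed between the states by less than the spread of the libraries. They held 33.3% ± 3.45 of cells in growing tumours and 34.8% ± 8.29 in regressing tumours (exact p = 1.0). Activated Exhausted held 17.1% ± 2.29 against 18.6% ± 4.42, and Alternative Exhausted 16.1% ± 1.16 against 16.2% ± 5.45. Cells at Initial Activation averaged 12.7% ± 4.37 in growing and 21.3% ± 10.9 in regressing tumours, with regressing replicate 1 at 33.8%. Without that library the difference was -2.37 percentage points in place of -8.63. Highest Activated cells held 8.92% ± 1.78 against 10.6% ± 1.91, and Intermediate Activation cells 10.9% ± 1.68 against 11% ± 0.111. Naive clusters were small in tumours. Naive 3 held 4.98% ± 2.93 in growing and 2.58% ± 1.54 in regressing tumours, Naive 1 held 0.339% ± 0.312 against 0.0497% ± 0.0653, and Naive 2 held 0.166% ± 0.212 against 0.0293% ± 0.0303. No Naive 1 cell was seen in regressing replicate 1, which allows a share of up to 0.181%, and no Naive 2 cell in regressing replicate 2 or growing replicate 1, which allows up to 0.0383% and 0.168%. NKT-like cells held 0.928% ± 1.07 against 1.12% ± 0.860. In all of these clusters the libraries of the states overlapped. The Naive 3 difference of 2.40 percentage points was 0.857 without growing replicate 2, 1.54 without regressing replicate 1 and 3.78 without growing replicate 1. Without each library in turn the Highest Activated difference ranged from -2.72 to -0.644 and the Activated Exhausted one from -4.04 to -0.0352 percentage points. The Naive 2 difference of 0.137 percentage points ranged from 0.0176 to 0.220. In pairs of libraries of the same number, Initial Activation was lower in the growing tumour in 3 of 3 pairs (by 16.2, 5.11 and 4.60 percentage points), and Naive 3 and Naive 1 were higher in 3 of 3 (exact sign-flip p = 0.25 each, the smallest that 3 pairs allow).

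A two-sided exact permutation test of 3 libraries against 3 cannot go below p = 0.10, and it gave p = 0.10 for each of the 4 separated clusters (adjusted p = 0.325 over 13 clusters). The dividing share differed by 12.2 percentage points over all libraries. It was 26.3% against 12.2% in the pair of 3′ libraries, and 20.7% and 26.8% against 14.2% and 10.8% in the 5′ libraries. Median UMIs per cell averaged 8717 ± 2660 in growing and 5989 ± 974 in regressing libraries (exact p = 0.20). When all libraries were given the same mix of cells over strata of UMIs per cell, the dividing difference was 5.31 percentage points and the libraries overlapped (exact p = 0.30). With strata of UMIs relative to each library's own Activated Exhausted cells it was 8.54 percentage points without overlap. The interferon-stimulated difference of -2.81 percentage points was -2.14 over raw strata and -2.55 over relative ones, without overlap in either (exact p = 0.10 each). Under limma, Dividing 2 (adjusted p = 0.0257) and Dividing 3 (adjusted p = 0.0456) passed the threshold of 0.05. With the replicate number as a block in limma, Dividing 2 (adjusted p = 0.0258) and Naive 1 (adjusted p = 9.48e-04) did. Naive 1 rested on 0, 2 and 9 cells in regressing and 2, 9 and 12 in growing libraries, and its difference was 0.112 percentage points without growing replicate 3 in place of 0.290. That block also called median UMIs (adjusted p = 0.0103), which limma without it did not (adjusted p = 0.197). Without growing replicate 3 the difference in median UMIs was 1230 in place of 2728.

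Calls of cell-cycle phase were compared as well. G2M-phase cells made up 14.7% ± 1.22 of growing and 9.25% ± 0.639 of regressing tumour libraries (SD, n = 3 each), again without overlap (exact p = 0.10). G1-phase cells made up 58.3% ± 1.14 against 63.7% ± 0.837, lower in every growing library (exact p = 0.10). S-phase calls did not separate the states, at 27.0% ± 0.0835 against 27.0% ± 0.256. S-phase calls were not limited to Dividing clusters, and 23% of Activated Exhausted cells carried one. The median G2M score was -0.0536 ± 0.00174 in growing and -0.0608 ± 0.00138 in regressing tumours (exact p = 0.10, adjusted p = 0.333 over 5 measures). Median genes per cell were 2448 ± 480 against 1974 ± 222 (exact p = 0.20). With the replicate block, limma called median genes (adjusted p = 0.0127, a difference of 474 that was 202 without growing replicate 3), the G1 share (adjusted p = 0.0103) and the G2M share (adjusted p = 0.00542); the G1 and G2M shares also passed without the block (adjusted p = 0.00438 and 0.00364). The mitochondrial share of UMIs had medians of 1.91% ± 0.259 against 1.87% ± 0.129 (exact p = 0.80). Phase calls and scores can also carry depth and free RNA, which the per-cell table did not allow to be thinned or subtracted.

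Tumour T cells were compared with spleen T cells from libraries of the same state and number. The spleens were mainly naive: the 3 Naive clusters held 60.9% ± 8.61 of spleen cells and 4.26% ± 1.31 of tumour cells (SD, n = 3 each). The mean paired difference was -56.7 ± 7.36 percentage points, with the tumour lower in 3 of 3 pairs. Exhausted clusters held 37.6% ± 4.86 of tumour cells and 4.74% ± 1.97 of spleen cells, a paired difference of 32.9 ± 4.44 percentage points. Dividing clusters held 17.3% ± 8.43 against 2.78% ± 0.981, and Initial Activation 13.2% ± 3.33 against 4.48% ± 2.42, each higher in the tumour in 3 of 3 pairs. Without growing replicate 3 the mean paired difference in dividing cells was 9.16 percentage points in place of 14.5. NKT-like cells held 1.10% ± 0.893 of tumour and 2.73% ± 1.52 of spleen cells, lower in the tumour in 3 of 3 pairs. Intermediate Activation (11.6% ± 0.932 against 12.4% ± 1.02) and Highest Activated cells (10.4% ± 2.28 against 8.68% ± 1.59) differed by -0.808 ± 0.394 and 1.67 ± 2.33 percentage points, the first lower in the tumour in 3 of 3 pairs. The Highest Activated difference was 0.382 without regressing replicate 2 and 2.65 without regressing replicate 3, and the NKT-like one was -0.856 without regressing replicate 3 in place of -1.63. An exact sign-flip test of 3 pairs cannot go below p = 0.25, which it gave for each of these classes except Highest Activated (p = 0.50). Without pairing, the 4 tumour libraries of the 5′ kit against the 3 spleens gave an exact permutation p = 0.0286 for naive, exhausted and Initial Activation cells, the smallest it allows, and p = 0.0571 for dividing cells. These libraries are not independent where tumour and spleen came from 1 mouse.

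The spleen of the mouse with a growing tumour held smaller shares of exhausted, dividing and interferon-stimulated cells than the 2 spleens of mice with regressing tumours. Exhausted clusters made up 2.46% of its cells (exact 95% interval 2.00 to 3), against 5.96% (5.40 to 6.55) and 5.80% (5.22 to 6.42) in regressing replicates 2 and 3. Dividing clusters made up 1.65% (1.28 to 2.10), against 3.29% (2.87 to 3.75) and 3.41% (2.96 to 3.89). The interferon-stimulated cluster made up 1.85% (1.46 to 2.32), against 3.49% (3.06 to 3.96) and 4.37% (3.87 to 4.92). Naive clusters made up 69.7% (68.3 to 71.2), against 60.6% (59.4 to 61.7) and 52.5% (51.3 to 53.8). Intermediate Activation was higher, at 13.5% (12.5 to 14.6) against 11.5% (10.7 to 12.3) and 12.2% (11.4 to 13.1). With 1 growing spleen no test was made, and the intervals cover counting error only.

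T cell clones were followed through CDR3 sequences, the part of the receptor that contacts antigen. In the 4 tumour libraries with receptor labels, 4183 and 4940 cells of regressing replicates 2 and 3 and 3177 and 1296 cells of growing replicates 2 and 3 carried a label. The authors named 71 clonotypes in tumour cells and pooled the remaining labelled cells. A receptor pair read with a second alpha chain has its own name. It was counted as a separate clonotype, except where the beta chain alone was used. Named clonotypes held 61.9% and 78.0% of labelled cells in regressing replicates 2 and 3, and 50.6% and 75.7% in growing replicates 2 and 3. The largest clone of regressing replicate 3, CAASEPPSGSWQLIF_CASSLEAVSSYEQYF, alone held 43.3% of labelled cells (2137 cells, exact 95% interval 41.9 to 44.6). A further 153 cells there carried this pair with a second alpha chain. The largest clones of the others held 13.4% in regressing replicate 2 (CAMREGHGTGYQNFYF_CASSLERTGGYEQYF), 15.5% in growing replicate 2 (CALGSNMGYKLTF_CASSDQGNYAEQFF) and 19.2% in growing replicate 3 (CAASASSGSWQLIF_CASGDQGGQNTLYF). The next largest clones held 6.29% and 5.38% in regressing replicate 2 (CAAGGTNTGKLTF_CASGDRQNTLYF and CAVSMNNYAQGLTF_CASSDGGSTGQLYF) and 4.74% and 3.42% in regressing replicate 3 (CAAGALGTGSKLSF_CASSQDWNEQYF and CALSEDYSNNRLTL_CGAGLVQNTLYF). They held 5.10% and 4.34% in growing replicate 2 (CAVSTDYSNNRLTL_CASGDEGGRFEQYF and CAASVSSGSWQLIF_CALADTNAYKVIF_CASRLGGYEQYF) and 11.9% and 6.94% in growing replicate 3 (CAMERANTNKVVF_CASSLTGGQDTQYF and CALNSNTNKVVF_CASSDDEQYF).

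**Figure D2:**
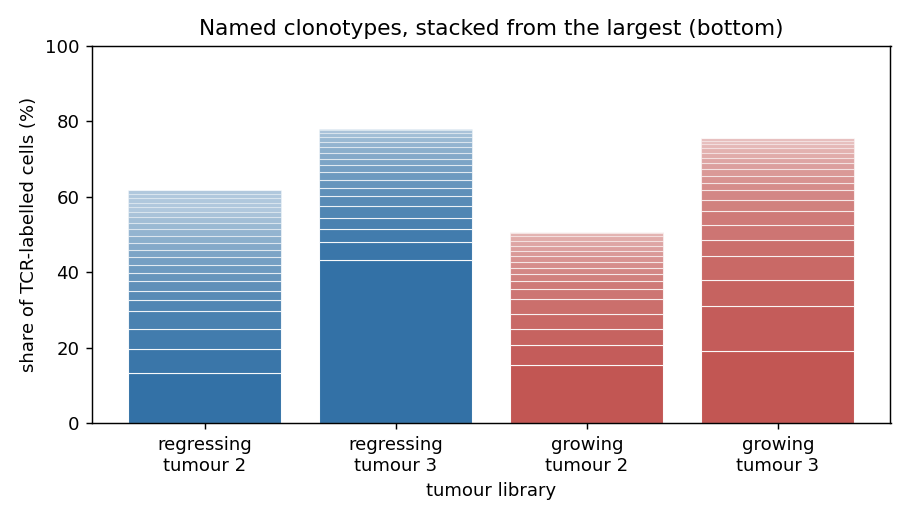
Share of receptor-labelled cells (%, vertical axis) held by each named clonotype in the 4 tumour libraries with labels (horizontal axis), stacked from the largest clone at the bottom, blue for regressing and red for growing tumours. The largest clone of regressing replicate 3 holds 43.3% of its labelled cells, and those of the other libraries hold 13.4% to 19.2%.

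After thinning each library to 1296 labelled cells, named clonotypes held 69.9% ± 11.4 of cells in regressing and 63.2% ± 17.7 in growing tumours (SD, n = 2 each, exact p = 0.667). The names were fixed before thinning, so thinning cannot correct the named share for the size of a library. Among named clones of 10 or more cells, the smallest had 41 and 44 cells in regressing and 25 and 13 in growing replicates 2 and 3. The largest clone held 28.3% ± 21.1 against 17.3% ± 2.64 (exact p = 1.0), and the 10 largest held 56.6% ± 17.1 against 53.3% ± 14.6 (exact p = 0.667). The regressing libraries differed from each other by more than the states did in each measure, and the smallest p that 2 libraries against 2 allow is 0.333. The sign of each of these differences turned when regressing replicate 3 was left out, to 1.31, 3.94 and 8.83 percentage points. Without growing replicate 2 the named share and the 10 largest clones turned as well, to 5.81 and 7.09 percentage points.

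Identical receptors appeared in different mice. Of the 71 named clonotypes, 8 occurred in at least 2 tumour libraries, and 5 of these had 5 or more cells in at least 2 of them. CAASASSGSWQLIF_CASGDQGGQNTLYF, the largest clone of growing replicate 3 with 249 cells, also had 100 cells in regressing replicate 2. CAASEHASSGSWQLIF_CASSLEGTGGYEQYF had 108 cells in regressing replicate 2, 7 in regressing replicate 3 and 81 in growing replicate 2. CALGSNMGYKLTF_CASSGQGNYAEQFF had 102 cells in regressing replicate 3 and 53 in growing replicate 2, where 43 more carried this pair with a second alpha chain. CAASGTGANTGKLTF_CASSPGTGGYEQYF had 69 and 8 cells in growing replicates 2 and 3. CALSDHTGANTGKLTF_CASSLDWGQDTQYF was seen in all 4 libraries, with 6 and 66 cells in regressing replicates 2 and 3 and 2 and 1 in growing replicates 2 and 3. In growing replicate 2, 7 more cells carried this pair with a second alpha chain. Pairs of libraries shared between 2 and 4 named clonotypes, with Jaccard indices from 0.0476 to 0.103, and no shared clonotype had a cell barcode in common between libraries. By the beta chain alone, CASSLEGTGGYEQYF was found in all 4 tumours, with 384, 257, 81 and 47 cells. Clonotype names were given for tumour cells only, so spleen and tumour clones were not matched here.

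Within clonotypes present in both states, the dividing share was higher in the growing tumour in 3 of 3 clonotypes with 20 or more cells on each side. For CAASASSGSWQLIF_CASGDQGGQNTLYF it was 41.0% in growing replicate 3 (exact 95% interval 34.8 to 47.4) and 15% in regressing replicate 2 (8.65 to 23.5). For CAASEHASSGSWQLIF_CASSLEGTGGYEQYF it was 27.2% in growing replicate 2 (17.9 to 38.2) and 18.5% in regressing replicate 2 (11.7 to 27.1). For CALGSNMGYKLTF_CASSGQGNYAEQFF it was 32.1% in growing replicate 2 (19.9 to 46.3) and 18.6% in regressing replicate 3 (11.6 to 27.6). Fisher's exact test on cells, which compares the libraries and not the states, gave adjusted p = 1.3e-05, 0.219 and 0.144 over 8 such comparisons. Exhausted clusters took 48.2%, 48.1% and 47.2% of these clonotypes' cells in the growing tumours, against 40%, 20.4% and 22.5% in the regressing ones. For these, Fisher's exact test on cells, again between libraries, gave adjusted p = 0.219, 2.99e-04 and 0.00827.

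**Figure D3:**
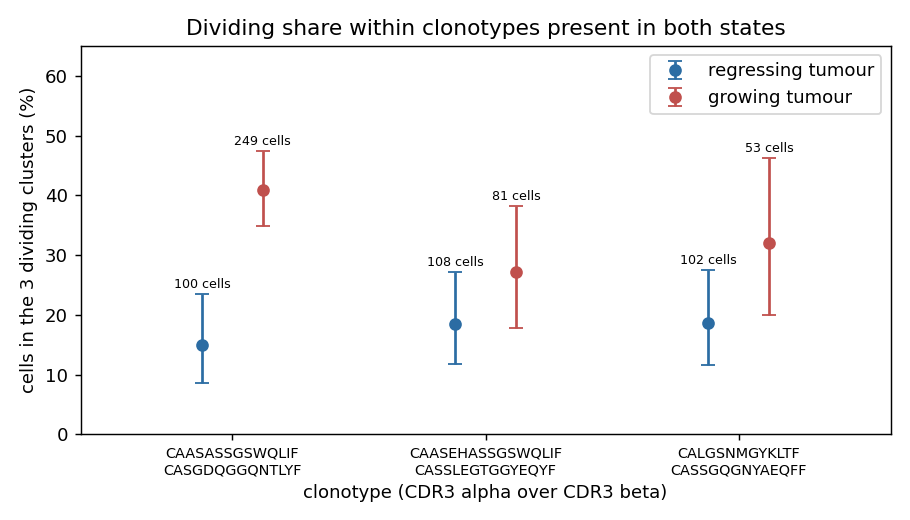
Share of cells in the 3 Dividing clusters (%, vertical axis) for 3 clonotypes (horizontal axis) with 20 or more cells in a regressing (blue) and a growing (red) tumour library, with exact 95% binomial intervals and cell numbers. All 3 red points lie above the blue ones, and the intervals part only for the left clonotype, at 41.0% against 15%.

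Cells of named clonotypes sat in exhausted clusters more often than the pooled remaining cells did, in all 4 tumours. Of cells in named clonotypes, 38.8%, 54.9%, 50.8% and 43.9% were in exhausted clusters in regressing replicates 2 and 3 and growing replicates 2 and 3. Of the remaining labelled cells, 25.5%, 17.3%, 26.2% and 18.1% were. The mean difference was 25.4 ± 9.95 percentage points (exact sign-flip p = 0.125, the smallest that 4 libraries allow). Activated Exhausted was higher among named-clone cells in 4 of 4 libraries and Alternative Exhausted in 3 of 4. In regressing replicate 2 the latter held 10.7% of named-clone cells and 12.5% of the remaining ones. The dividing clusters differed less, by 3.05 ± 3.49 percentage points, and by 1.37 without growing replicate 3, where the difference was 8.08. Naive clusters held 0.116% to 0.204% of named-clone cells and 10.7% to 15.9% of the remaining labelled cells. Seen by cluster, named clonotypes held 81.5% ± 14.6 of labelled exhausted cells in regressing and 77.4% ± 15.4 in growing tumours (n = 2 each, exact p = 0.667), a difference that turned to 6.26 percentage points without regressing replicate 3 and to 6.81 without growing replicate 2. They held 71.7% ± 8.94 of dividing cells against 67.5% ± 20 (exact p = 1.0), a difference that turned to 2.11 percentage points without regressing replicate 3 and to 9.96 without growing replicate 2. In Initial Activation they held 58.7% ± 6.56 against 39.4% ± 19.9 (exact p = 0.333, the smallest possible), a difference of -19.3 percentage points that was -5.17 without growing replicate 2 and -33.4 without growing replicate 3.

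The A223 line was read for variants against a mouse reference whose build is not given in the sources used here, with positions that fell within the GRCm38.p6 bounds of their genes for 99.3% of coding calls. The exome gave 209790 variant calls, of which 59.8% (exact 95% interval 59.6 to 60.0) were homozygous. Base substitutions made up 176184 of them, with 2.14 transitions per transversion. C-to-T changes made up 34.4% (34.2 to 34.6) and T-to-C changes 33.8% (33.6 to 34), counted on either strand. Missense calls numbered 8079 and synonymous calls 12771, a ratio of 0.633. There were 318 frameshift, 237 in-frame insertion or deletion, 136 splice donor or acceptor and 79 stop-gained calls. Protein-changing calls numbered 8733 in 2740 genes.

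Calls were spread unevenly over the chromosomes. Chromosomes 8 and 7 held 10.9% (10.7 to 11) and 9.79% (9.66 to 9.92) of exome calls, and chromosome 2 held 0.991% (0.949 to 1.03). Homozygous calls made up 93.2% (92.9 to 93.6) on chromosome 8 and 92.6% (91.9 to 93.3) on chromosome 12. They made up 21.0% (20.1 to 22.0) on chromosome 19 and 26.1% (25.2 to 27.0) on chromosome 14. In windows of 5 Mb, 62 windows with 100 or more coding calls held 13229 coding calls, and 331 windows with 20 or fewer held 1315. The window with the most coding calls, from 170 to 175 Mb of chromosome 1, held 815.

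**Figure D4:**
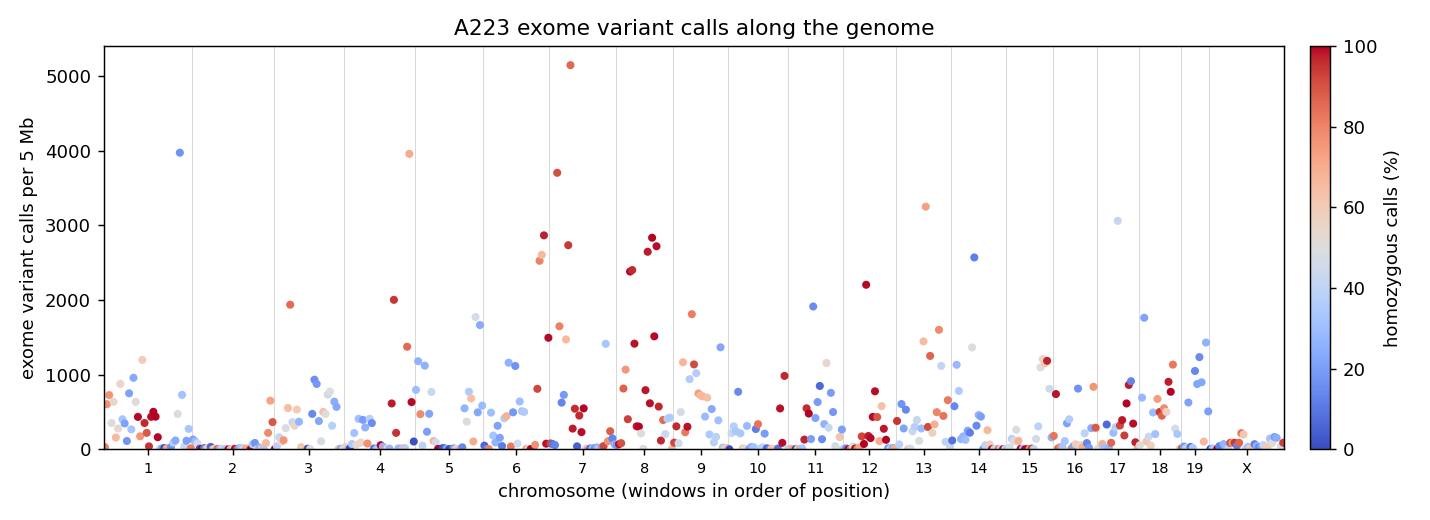
Exome variant calls per 5 Mb window (vertical axis) along chromosomes 1 to 19 and X (horizontal axis, windows in order of position), coloured by the share of homozygous calls from blue (0%) to red (100%). Windows with many calls stand in runs between windows with few, and most windows of chromosome 8 with many calls are red, with 93.2% of its calls homozygous.

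Genes of antigen presentation, interferon response, DNA repair and squamous carcinoma carried protein-changing exome calls. The series holds no normal DNA beside A223, and known strain polymorphisms were not removed here. No single A223 call can therefore be assigned to inheritance or to a mutation gained in the tumour. Over the calls as a set, a gene 10 places from one with a coding call had one in 37.0% of cases. Of all protein-coding genes 18.5% had one, which argues against mutations scattered over genes. The window that holds Nlrc5, from 90 to 95 Mb of chromosome 8, had 2722 exome calls, of which 99.0% were homozygous. In the antigen presentation list 4 genes had 17 calls. Nlrc5, the transactivator of MHC class I genes, carried 11 homozygous missense calls on chromosome 8, among them S489A at position 94476738 and F490S at 94476742, both read in RNA at depths of 60 and 61. Tapbpl, a tapasin relative, carried 3 homozygous missense calls. H2-Q6 (2 calls) and H2-Q7 (1 call), near-identical class I genes whose reads are hard to place, had no RNA call. In the interferon list, Tyk2 and Stat2, kinase and transcription factor of interferon signalling, carried 3 homozygous calls each. Irf2 carried homozygous D295E and the interferon gamma receptor gene Ifngr1 heterozygous E95G, read in RNA at depths of 77 and 90. The 3 Stat2 calls had no RNA call at depths of up to 48.

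In the DNA repair list 11 genes had 45 calls. Brca2 had 20 and the nucleotide excision repair gene Ercc5 had 12, all heterozygous. The mismatch repair gene Msh3 had 4, and Fancm 2, all homozygous, and Pold1 had homozygous D744N. Atm (I2294L), Atr (L302V), Brca1 (E1510K), Chek2 (S521G), Polh (Y105H) and Xpa (K244E) had 1 heterozygous missense call each, of which those in Brca1 and Chek2 were not called in RNA at depths of 58 and 37. In the squamous carcinoma list 6 genes had 10 calls, all heterozygous. Fat2 had 3 calls, Casp8 had 2 (Q13R and A116V) and the histone methyltransferase gene Kmt2d had 2. Notch2 (S255N), the hedgehog receptor gene Ptch1 (T1267N) and Sox2 (an in-frame deletion) had 1 each.

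Against all 23793 genes with any variant, of which 11.5% carried a protein-changing exome call, the DNA repair list stood out, with 11 of 30 genes (36.7%, odds ratio 4.46, Fisher's exact adjusted p = 0.00437 over 14 lists). Against genes with a coding variant, of which 49.3% carried one, the DNA repair list had an odds ratio of 1.89 (Fisher's exact adjusted p = 0.628). The interferon list had 4 of 15 genes (Fisher's exact adjusted p = 0.269), the antigen presentation list 4 of 18 (adjusted p = 0.290) and the squamous carcinoma list 6 of 40 (adjusted p = 0.532). Of the short T cell and cell type lists, none passed the test. The cycling and interferon-stimulated lists had 2 of 2 genes each (Fisher's exact adjusted p = 0.0619), and the naive list 0 of 5. The effector, exhausted, CD4 or regulatory, B cell, myeloid and NK lists had 1 gene each, and no keratinocyte list gene was in the background.

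RNA of the same cells recovered most exome calls where it was read deeply, but few calls were. The median RNA depth at exome calls was 0, and 38182 of 209790 were called in RNA. Of 393066 RNA calls, 354884 had no exome call. At 20 or more RNA reads, 73.7% of 14310 exome calls were also called in RNA (exact 95% interval 73.0 to 74.4), and 86.4% of those had the same genotype. The share called in RNA was 76.2% at 10 or more reads and 67.3% at 50 or more. Of homozygous protein-changing exome calls at 20 or more reads, 93.0% (90.7 to 94.9) were homozygous in RNA. Of heterozygous protein-changing calls, 62.2% (59.6 to 64.7) were heterozygous in RNA, 6.12% (4.92 to 7.52) were homozygous and 31.7% (29.3 to 34.2) were not called. For heterozygous synonymous calls, 74.6% (72.9 to 76.3) were heterozygous in RNA. Over exome calls of all classes at 20 or more reads these shares were lower. Of homozygous calls 78.0% were homozygous in RNA, and of heterozygous calls 54.7% were heterozygous. Allele read counts and exome depth were not used here, so these are agreements of genotype calls from 1 library each and not allele fractions.

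Among protein-changing calls made in both DNA and RNA, the 20 with the most RNA reads were all missense and lay in 12 genes. The deepest were A40T in the mitochondrial serine hydroxymethyltransferase gene Shmt2 (chromosome 10, position 127521031, 1266 reads) and A190G in the linker histone gene H1f0 (chromosome 15, position 79029290, 1259 reads), both homozygous. Prune2 on chromosome 19 carried 6 heterozygous changes, among them T2183A with 857 reads. Ppp1r15a, a regulator of the stress-induced block of translation, carried 4 homozygous changes, V635A, E451D, D459N and K244R, with 499 to 657 reads. The mitochondrial chaperone gene Hspa9 (D626G, 956 reads), Rad23b (A98T, 730 reads), Tspo (P168A, 722 reads) and Gpnmb (D36N, 560 reads) were heterozygous in DNA and RNA. Emp3 (T154I, 925 reads), the mitochondrial protease gene Lonp1 (G240S, 880 reads) and Eps8 (N652D, 423 reads) were homozygous in both. Tpm3-rs7 (K43E, 500 reads), a copy of a tropomyosin gene, was heterozygous in DNA and homozygous in RNA, and its reads are hard to separate from those of the parent gene.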

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

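Of the tests in this part, the UMI strata, the share of naive and NKT-like cells, the comparison within clonotypes and limma with a replicate block were chosen after the result was seen.

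Dividing clusters and G2M calls went opposite ways in tumours and spleens. Every growing tumour held a larger share of dividing cells than every regressing tumour, and the 1 growing spleen held a smaller share than both regressing spleens. In the spleens the growing minus regressing difference was -1.70 percentage points for dividing cells, with -0.478 for Dividing 1, -0.631 for Dividing 2 and -0.588 for Dividing 3. G2M-phase cells differed by -1.10 and G1-phase cells by 4.07 percentage points. The difference between the tissues was not tested.

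Naive and NKT-like cells made up 2.68%, 10.5% and 6.02% of growing tumours and 1.27%, 5.89% and 4.18% of regressing ones, more in the growing tumour in 3 of 3 pairs, so a smaller share of them could not have raised the dividing share, and leaving them out gave a difference of 13.3 percentage points. Within 3 shared clonotypes the common odds ratio of dividing was 2.60 (1.78 to 3.82), but the interval covers the counting of cells only, each clonotype sets 1 library against 1 and 1 of 3 passed alone, so different clones stay open. With strata of UMIs relative to each library's Activated Exhausted cells the difference was 8.54 percentage points and every growing library stayed higher, but with strata of raw UMIs it was 5.31 and the libraries overlapped, so library depth may account for part or most of it, although Dividing 2 cells, with a median of 13378 UMIs against 6757 in Activated Exhausted cells, would lose part of a real difference in such strata. Limma called 2 clusters, Dividing 2 and Dividing 3, and 2 measures, with at most 1 and 0 in the other splits, and with the block 2 clusters, of which Naive 1 is no dividing one, and 4 measures, of which 2 measure depth, with at most 0 and 0; the 10 splits, or the 4 that part all 3 pairs, are too few for a share under 0.05, and the real split alone gave as many, 1 of 10 or 1 of 4. The tumour state itself stays open as a biological explanation, and doublets and free RNA in the phase calls could not be tested.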

How the results depend on the processing

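Limma with a replicate block, the UMI strata and the leaving out of naive cells were chosen after the data were seen. Without each library in turn, the dividing difference ranged from 11.1 to 14.2 percentage points, the interferon-stimulated one from -3.41 to -1.98 and the G2M one from 4.95 to 6.14. Under the replicate block the dividing difference was 12.2 (exact sign-flip p = 0.25), a test that cannot pass 0.05. With raw UMI strata it was 5.31 (exact p = 0.30). Of values under alternatives, 7 of the main results and 20 of the others turned in direction. Most of the remaining ones rest on exact tests that cannot pass 0.05, so they speak of direction alone. Without pairing, tumour minus spleen was -55.7 for naive and 32.3 for exhausted cells (exact p = 0.0286 each), past 0.05 because 4 libraries against 3 allow it.

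Limma called 2 clusters and 2 per-cell measures where the exact tests, at their smallest p, called 0, and with the block 2 and 4. The 2 measures were the G1 and G2M shares, which partly recount the Dividing clusters. Limma adjusted the phase shares together with the medians, whereas the exact tests adjusted the medians with the S and G2M scores. The G2M difference under limma was 0.526 on the logit scale. Clusters without overlap numbered 10 in the 5′ libraries alone and 4 to 9 without each library (9 without growing replicate 1), where fewer samples make separation by chance more frequent. Alternative Exhausted turned to 0.030 (logit) under limma, and Intermediate Activation to 0.530 in the 5′ libraries alone. Clonotypes shared at 2 or more cells numbered 5, since fewer cells pass. Exome calls found in RNA moved to 76.2% at 10 reads and 67.3% at 50, and the cause was not tested. Against genes with a coding variant 0 lists passed, and odds ratios were 0.684 for antigen presentation and 0.384 for squamous carcinoma, with fewer genes tested.

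Without each library in turn, these differences between states took both signs, and the cause was not tested: Alternative Exhausted from -1.64 to 3.12, Intermediate Activation from -1.05 to 0.593, NKT-like from -0.810 to 0.272, exhausted from -5.60 to 2.69, S phase from -0.221 to 0.0318 and mitochondrial percent from -0.102 to 0.144. So did the share of named clones, from -19.3 to 5.81, of the largest clone, from -25.8 to 3.94, and of the 10 largest, from -15.3 to 8.83. The named share also did within exhausted cells, from -14.9 to 6.81, within dividing cells, from -18.4 to 9.96, and within naive cells, from -3.20 to 0.858.

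The cell filter removed no cell and gave no alternative. Clones of 3 or more cells, entropy, exome depth, allele fraction and known polymorphisms were not run, for lack of the values they need. Precision is limited by 3 libraries per tumour state, 2 with receptor labels and 1 growing spleen.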

Other observations

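Of the tests in this part, the 4 on splice-site calls were chosen after the result was seen, and the 2 on neighbouring genes and the windows sorted by non-coding calls were added after the first test on windows but before their own values were seen.

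The authors also sorted receptors into 10 groups of similar sequence, a sign of possible shared antigen. In tumours 45.1% and 65.6% of labelled cells of regressing replicates 2 and 3 and 52.5% and 50.9% of growing replicates 2 and 3 fell in a group. Group 1 was in all 4 tumours, at 27.6% and 5.57% in regressing and 8.97% and 6.56% in growing ones. Group 2 held 50.4% of cells in regressing replicate 3, with 1 cell in growing replicate 3 and 0 in the other tumours, which allows up to 0.0717% and 0.0944%. Group 9 held 6.93% and 3.89% in regressing tumours against 0.283% and 0 of 1296 cells, which allows up to 0.231%. Group 5 held 1.46% and 0.263% against 5.85% and 12.7%. Single clones weighed heavily in these shares. The beta chain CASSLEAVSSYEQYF was in 2374 of the 2489 Group 2 cells of regressing replicate 3. A single clone held 263 of 290 and 169 of 192 Group 9 cells in regressing replicates 2 and 3. Another held 125 of 186 Group 5 cells in growing replicate 2, and another 154 of 164 in growing replicate 3. Alpha chains ending in SGSWQLIF made up 31.2% and 69.6% of named-clone cells in regressing and 15.9% and 32.3% in growing tumours. In regressing replicate 3 a single clone held 2137 of the 2680 cells with this ending, and in growing replicate 3 a single clone held 249 of 317. Without the largest such clone name of each library the shares were 25.5% and 31.7% against 8.02% and 9.29%. Only the exact name was left out. The same pair stayed in with a second alpha chain in regressing replicate 3 (153 cells) and without one in growing replicate 2 (37 cells). Other clones with the beta chain of the removed one also stayed in, with 108 and 77 cells in regressing replicate 2 and 84 in regressing replicate 3. These shares therefore still carry part of the removed clones. Of 6 receptor groups with 20 or more cells in a library of each state, 5 had a higher dividing share in growing tumours. The exception was Group 8, with 9.96% against 21.1%. Groups 1, 3 and 4 hold the 3 shared clonotypes of the report, so these counts are not separate evidence.

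Spleens of mice with regressing tumours held clones that the authors labelled as top spleen clones. They made up 7.38% (exact 95% interval 6.61 to 8.21) and 9.56% (8.68 to 10.5) of labelled cells in regressing replicates 2 and 3 and 0.365% (0.175 to 0.671) in growing replicate 3. Of these cells 42.3% and 32.1% sat in exhausted clusters in the regressing spleens, against 2.36% and 2.64% of the remaining cells. Receptor groups covered 7.88% and 9.18% of cells in the regressing spleens and 0.841% in the growing one. Heterozygous exome sites were read as heterozygous in RNA at shares from 3.95% on chromosome 12 (76 sites) and 6.13% on chromosome X (163 sites) to 75.1% on chromosome 9. Among genes with many missense calls were the inflammasome gene Nlrp1b (128), Mrgpra4 (83), Skint5 (80) and Cd244, a receptor of NK cells (66). These genes, the alpha chain ending and the chromosomes were picked after their values were seen.

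Exome calls of A223 stood in dense blocks. A gene 10 places from a gene with a coding call had one in 37.0% of cases, 18.5 percentage points above all genes, which argues against mutations scattered over genes and is consistent with inherited segments. Neighbouring calls in dense windows shared zygosity 31.0 percentage points more often than the genotype shares of the whole chromosome give. The excess was 32.1 in the windows between and 29.6 in sparse ones, so it is not special to dense blocks. Zygosity that differs between regions of a chromosome gives such an excess however the calls arose. The excess therefore does not decide for or against mutations gained one by one. Strain polymorphism had been predicted to lower missense per synonymous calls in dense windows, and that prediction failed, with 0.709 against 0.547 in sparse ones, though with windows as the unit the intervals overlapped (0.623 to 0.806 and 0.472 to 0.631). With windows sorted by non-coding calls the ratios were 0.663 (0.574 to 0.760) and 0.647 (0.540 to 0.788). These intervals overlap, so the difference between windows does not decide for or against strain polymorphism. The level of the ratio itself, 0.633 over all exome calls, was not tested against an expected value.

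Calls at splice donor or acceptor sites were almost all in RNA alone, 10200 against 136 in the exome. Of base substitutions at sites next to coding sequence 95.9% were in RNA alone, against 6.19% of missense and synonymous ones, which argues against substitutions that the exome missed. Of insertions and deletions 99.4% were, but so were 81.6% of those in coding sequence, so DNA variants that the exome missed stay open for these. A-to-G changes on the transcript strand made up 0.588% of the RNA-only calls, of which 89.4% were insertions or deletions, and 5.55% of their 1082 base changes, which argues against RNA editing of A to I as the cause. The share in RNA alone was 14.1 times that of missense calls. Reads laid across exon junctions without splicing stay open. Coding insertions and deletions were also mostly in RNA alone, and the test cannot tell whether these arose in the same way. The labels name BWA for the A223 reads, and how it laid reads across junctions was not examined.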
